A study of Mus musculus with 30 samples.

How the data were processed

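DNA was treated with bisulfite (Zymo EZ DNA Methylation-Lightning chemistry), amplified by nested locus-specific PCR and sequenced as amplicons on the Oxford Nanopore platform by Plasmidsaurus, per the labels' protocols. Bisulfite treatment does not separate 5-methylcytosine from 5-hydroxymethylcytosine. Each of the 30 deposited files holds 1 library and gives, per read and CpG, 1 call as methylated or unmethylated on the original top strand. The calls were written by the Bismark methylation extractor, version 0.22.3 per the file headers, while the submitters' processing notes name Bismark 0.24.2 and mm10. Aligner settings and read filters are not given in the sources used here.

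The reads were aligned to 4 amplicon references, not to chromosomes, as the reference names in the files show. The IG-CGI reference has 29 CpGs at positions 55 to 273 (17 libraries), the reporter IG-CGI reference has 28 at 39 to 259 (3 libraries), the IG-TRE reference has 7 at 58 to 339 (4 libraries) and the Gtl2-DMR reference has 15 at 33 to 339 (6 libraries). At an offset of 16 bases, 26 of the 28 reporter CpGs have the spacing of the endogenous reference, so equal CpG numbers in these amplicons are not the same CpG. The design had assumed a block of chromosome 12. An amplicon CpG was instead taken as a position with calls in at least 10% of the reads of any library on that reference, and other positions held at most 0.414% of a library's calls. Sequence lists for Zfp57 and Gzf1 motifs had been planned, and were not used because no amplicon or genome sequence was at hand. Gene coordinates are from the RefSeq table of the mm10 assembly.

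Groups followed the genotype, tissue and locus labels. The dead pup carries the adult tail tissue label, and its group follows its title. The submitters' naming shows 12 sequencing orders. In 7 of the 16 comparisons all libraries came from 1 order, and in the other 9 order and genotype were not separated, namely mESC at the IG-CGI and Gtl2-DMR, reporter knockouts against wild type, oocytes, heterozygous tails and the dead pup. The read names carry a running number, and the reads with calls amounted to 3.26% to 38.4% of its highest value at the IG-CGI, 6.76% to 7.77% at the IG-TRE and 1.21% to 3.23% at the Gtl2-DMR. Only CpG calls are in these files, so conversion was not checked at other cytosines.

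The methylation level of a CpG is the percentage of its calls that are methylated. The level of a library is the mean over CpGs with at least 10 calls. Intervals at 95% come from 1000 resamples of whole reads. CpGs with at least 10 calls in both libraries were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within the pair, and called when the adjusted p was under 0.05 and the levels differed by at least 20 points. Higher, lower, rise and fall of a CpG refer to such calls. Where a group had several libraries, a CpG counted only if called the same way in each. Reads with at least 5 calls were classed as mostly methylated (at least 70% of calls), mostly unmethylated (at most 30%) or between, with Wilson intervals, and a count of 0 was given the limit of 3 counts. The text names, per comparison, the called CpG with the largest rise or fall, or without calls the CpG with the largest difference. CpG 231, CpG 131 and CpG 286 fall outside that rule and were singled out after their values were seen.

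Group means were compared by exact two-sided permutation tests. The 5 heterozygous libraries were tested in 10 pairs by permuting reads 1000 times. Of these pairs, 4 differed in CpG levels and 9 in read patterns, and all 10 in at least one of these. This covers counting error only, and libraries from 1 animal could differ as much. They were counted as 5 animals because the submitters' names number them as 5 pups. Animal numbers in the text are a running order, not the submitters' pup numbers. The oocyte knockout libraries differ by more than counting error.

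The tests were run on simulated reads at the real depths, in 50 simulated pairs per comparison. CpGs raised by 30 points were called in 100% of cases for mESC IG-CGI, 92.6% for the reporter, 98.7% for trunk IG-TRE, 69.4% for trunk Gtl2-DMR and 94.6% for adult tail Gtl2-DMR, and CpGs left level in 2% or fewer. The intervals held the simulated difference in 88% to 98% of pairs. Each simulated read was drawn independently from an equal mix of methylated and unmethylated copies. PCR copies of a molecule and variation between libraries were not simulated, so these rates do not cover them.

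Alternatives fixed before the data were examined were minimum coverages of 5 and 30 calls, minimum differences of 10 and 30 points, pooling of all calls, identical read patterns counted once, reads with at least 5 calls, calls at every position, other bounds for the read classes, and leaving out each replicate or source. Using only reads called at 50% or more of the CpGs for the mean difference was added after seeing the data. The software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.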

Results

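CpG methylation was measured at 3 amplicons of the imprinted Dlk1-Dio3 domain in 30 mouse libraries. The domain lies on chromosome 12 of mm10, between Dlk1 (109452485 to 109463336) and Dio3 (110279230 to 110281097), with the long non-coding RNA gene Meg3, also called Gtl2, at 109540996 to 109571729. The IG-CGI and the IG-TRE belong to the intergenic control region between Dlk1 and Meg3, and the Gtl2-DMR is the differentially methylated region at Meg3. In normal tissue the paternal copy of these regions is methylated and the maternal copy is not. The calls are numbered along the amplicon references, and the amplicons were not placed at genome coordinates here.

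The IG-CGI was read in 20 libraries, the IG-TRE in 4 and the Gtl2-DMR in 6. They came from embryonic stem cells (mESC), the trunk of E10.5 embryos, mature MII oocytes, adult tail and a pup found dead at birth. Genotypes were wild type and knockouts of Gzf1, a zinc finger protein (gene on chromosome 2, 148679384 to 148692949), Zfp57, a zinc finger protein that binds methylated imprinting control regions (chromosome 17, 37001163 to 37010729), Dnmt1, the maintenance methyltransferase, and the Tet family, which oxidises methylcytosine. Of the 25 groups, 23 had 1 library, the Gzf1 knockout oocytes had 2 and the heterozygous tails had 5. The amplicon reads do not measure expression of the deleted genes, so the genotypes rest on the labels.

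Depth differed between loci. The IG-CGI libraries held 163 to 1917 reads, the IG-TRE libraries 338 to 388 and the Gtl2-DMR libraries 60 to 160. Levels below are means over the CpGs of an amplicon, each CpG weighted equally, with 95% intervals from resampling reads. PCR reads without molecular identifiers are not independent molecules, so these intervals, the Wilson intervals and the limits set by counts of 0 cover counting error only. The p-values of Fisher's exact test count reads in the same way. The CpGs of an amplicon lie on the same reads, so calls at several CpGs are not independent of each other. In 14 of the 16 comparisons each group had 1 library, and the tests on reads then compare those libraries, not the conditions.

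**Figure D1:**
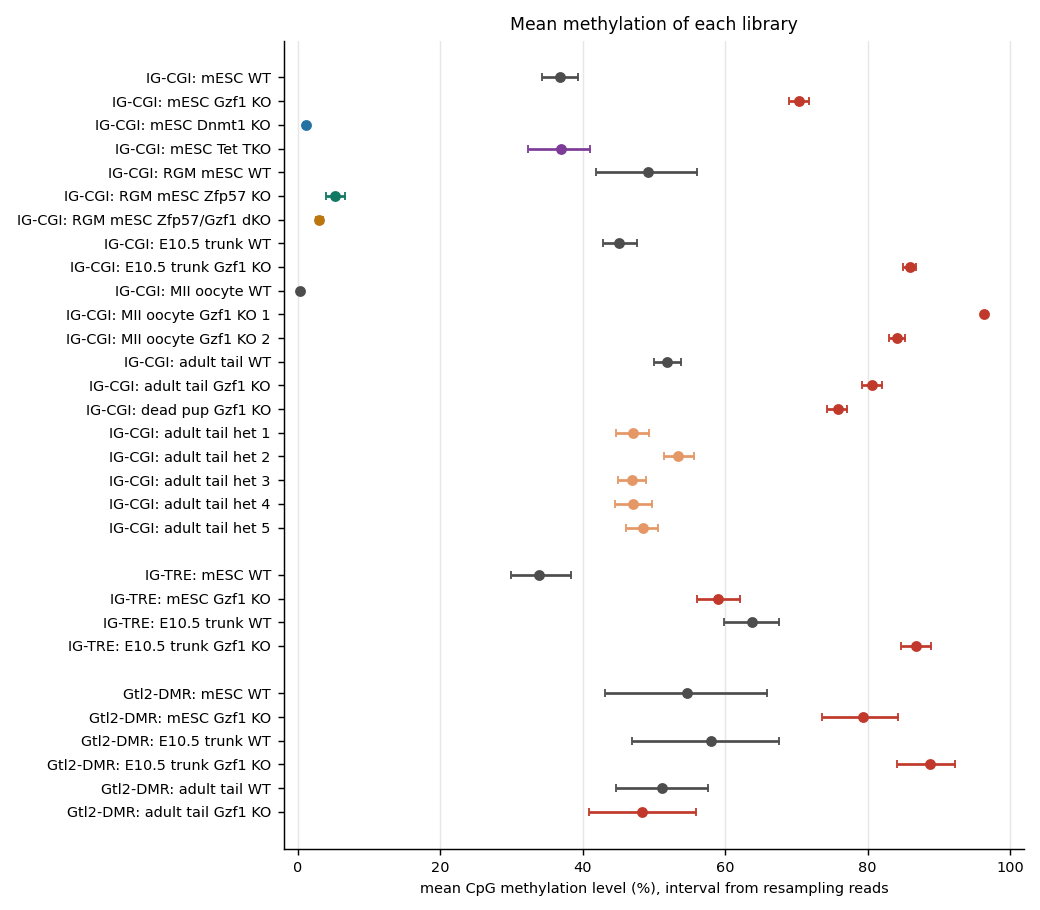
Mean CpG methylation level (%, horizontal axis) of each of the 30 libraries, grouped by amplicon, with 95% intervals from resampling reads. At the IG-CGI the libraries with knockout of Gzf1 alone lie between 70.4% and 96.3%, and the heterozygous tails lie between 46.9% and 53.4%. The reporter library without Zfp57 and Gzf1 lies at 3.00%.

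In V6.5 mESC, a mouse embryonic stem cell line, the IG-CGI was more methylated without Gzf1. The mean level was 36.8% in wild-type cells and 70.4% in Gzf1 knockout cells, a difference of 33.7 points (95% interval 30.8 to 36.4). Methylation was higher at 27 of 29 CpGs, and the largest rise was at CpG 214, from 37.3% to 82.1%. Reads with at least 70% of their calls methylated made up 34.5% of wild-type reads (Wilson interval 31.9 to 37.3) and 66.3% of knockout reads (64.1 to 68.4). Mostly unmethylated reads, with at most 30% of calls methylated, went from 60.2% to 15.2%, and reads between these bounds from 5.29% to 18.6%. The calls are from Fisher's exact test at each CpG with Benjamini-Hochberg adjustment, which gave an adjusted p of 5.42e-138 at CpG 214. With reads of identical call pattern counted once, the difference was 16.0 points and 7 CpGs were called.

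Loss of Dnmt1 removed nearly all methylation of the IG-CGI in V6.5 cells. The mean level was 1.09%, against 36.8% in wild type (difference -35.7 points, 95% interval -38.3 to -33.0), and all 29 CpGs were lower. The largest fall was at CpG 273, from 41.4% to 0.747%. Of 766 reads, 764 were mostly unmethylated and 2 were mostly methylated. In this library residual methylation and unconverted cytosine read as methylation add up to 1.09% at these CpGs. That bounds failed conversion in this library only.

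Tet triple knockout mESC had the wild-type level of the IG-CGI within counting error. The mean was 36.9%, a difference of 0.151 points (95% interval -5.09 to 5.00), and no CpG of 29 was called by Fisher's exact test, with 0 at an unadjusted p under 0.05. The largest difference was at CpG 180, with 40.5% against 37.0%. The split of reads was also close, with 36.7% mostly methylated (Wilson interval 32.2 to 41.5) and 60.1% mostly unmethylated (55.4 to 64.7). These cells are a line other than V6.5, so line and genotype were compared together.

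In mESC carrying the RGM reporter, the IG-CGI read on the reporter reference had little methylation without Zfp57. The mean level was 49.2% in wild-type reporter cells and 5.22% in Zfp57 knockout cells (difference -44.0 points, 95% interval -51.1 to -36.8), and all 28 CpGs of the reporter amplicon were lower. In cells without Zfp57 and Gzf1 the mean was 3.00% (difference from wild type -46.2, interval -53.5 to -38.7), again with 28 of 28 CpGs lower. The largest fall in either knockout was at CpG 215, from 62.4% to 2.15% without Zfp57 and to 0.658% without both proteins. Mostly methylated reads were 51.4% of wild-type reads (Wilson interval 44.1 to 58.6), 0 of 162 reads without Zfp57, which allows a share of up to 1.85%, and 0 of 350 reads without both, which allows up to 0.857%. The wild-type library had 182 reads, and its calls per CpG ranged from 49 to 176. CpG 215 had 85 calls there, so its level rests on part of the reads. The wild-type split changed when reads called at only the smaller part of the CpGs were left out. Mostly methylated reads were then 41.2%, below the Wilson interval, and the knockouts still had none. The mean differences stayed within their intervals, at -41.7 points without Zfp57 and -43.7 without both.

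Additional loss of Gzf1 did not raise the reporter IG-CGI in Zfp57 knockout cells. The double knockout lay slightly below the Zfp57 knockout (difference -2.21 points, 95% interval -3.88 to -0.739), and 22 of 28 CpGs were lower by value. The largest difference was at CpG 43, with 8.75% against 18.1%. No CpG differed by the 20 points required for a call; Fisher's exact test gave an unadjusted p under 0.05 at 7 CpGs and an adjusted p under 0.05 at 4. With identical patterns counted once the difference was -4.46 points.

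The gain of methylation in Gzf1 knockout mESC extended to the other 2 amplicons. At the IG-TRE the mean rose from 33.8% to 59.0%, by 25.2 points (95% interval 20.3 to 30.7), with 6 of 7 CpGs higher. CpG 58 had the largest rise, from 32.5% to 76.3%, and CpG 286 was the exception, at 32.5% in wild-type and 29.8% in knockout cells. At the Gtl2-DMR the mean rose from 54.7% to 79.4%, by 24.7 points (interval 12.6 to 37.1), with 11 of 15 CpGs higher and CpG 200 rising from 50.9% to 85.6%. Mostly unmethylated reads went from 60.0% to 22.6% at the IG-TRE and from 41.4% to 9.91% at the Gtl2-DMR.

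These mESC calls depended on the size required and on how repeated patterns were counted. With a minimum of 30 points, 3 CpGs of the IG-TRE and 4 of the Gtl2-DMR were called. With identical patterns counted once, the differences were 11.5 and 13.8 points and the calls 2 and 0, and the wild-type Gtl2-DMR library had 60 reads.

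In the trunk of E10.5 embryos the IG-CGI was methylated on most reads without Gzf1. The mean level was 45.1% in the wild-type and 85.9% in the knockout embryo library, a difference of 40.8 points (95% interval 38.3 to 43.5), and all 29 CpGs were higher. CpG 77 had the largest rise, from 44.6% to 95.2%. Mostly methylated reads went from 41.6% (Wilson interval 39.0 to 44.2) to 85.4% (83.7 to 86.9), and mostly unmethylated reads from 51.7% to 4.20%. No knockout read of 1857 was unmethylated at every call, which allows a share of up to 0.162%, against 24.1% of wild-type reads. With identical patterns counted once the difference was 25.7 points.

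The IG-TRE and the Gtl2-DMR were also more methylated in the knockout trunk. At the IG-TRE the mean went from 63.7% to 86.8%, by 23.1 points (95% interval 18.8 to 27.6), with 5 of 7 CpGs higher and the largest rise at CpG 339, from 60.9% to 92.3%. The wild-type IG-TRE reads did not split evenly. Of them, 53.1% were mostly methylated, 27.5% between and 19.3% mostly unmethylated. In wild-type mESC the IG-TRE reads leaned the other way, with 26.2% mostly methylated and 60.0% mostly unmethylated. CpG 286, level in mESC, was higher here, at 58.2% in wild type and 83.5% in the knockout. At the Gtl2-DMR the mean went from 58.0% to 88.8%, by 30.8 points (interval 19.9 to 42.7), with 11 of 15 CpGs higher. The largest rise was at CpG 334, from 31.3% to 93.3%, and mostly methylated reads went from 56.9% to 95.5%. One CpG of the IG-TRE was called with a minimum of 30 points, and likewise 1 with identical patterns counted once. The Gtl2-DMR libraries had 64 and 69 reads, a depth at which 69.4% of CpGs raised by 30 points in simulated data were called. Calls per CpG ranged from 16 to 62 in the wild-type Gtl2-DMR library, so the level of a single CpG can rest on few calls. CpG 334, named above for the largest rise, had the fewest there, 16. With a minimum of 30 calls, CpG 334 was left out, 10 CpGs of the Gtl2-DMR were called and the mean difference was 30.1 points.

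**Figure D2:**
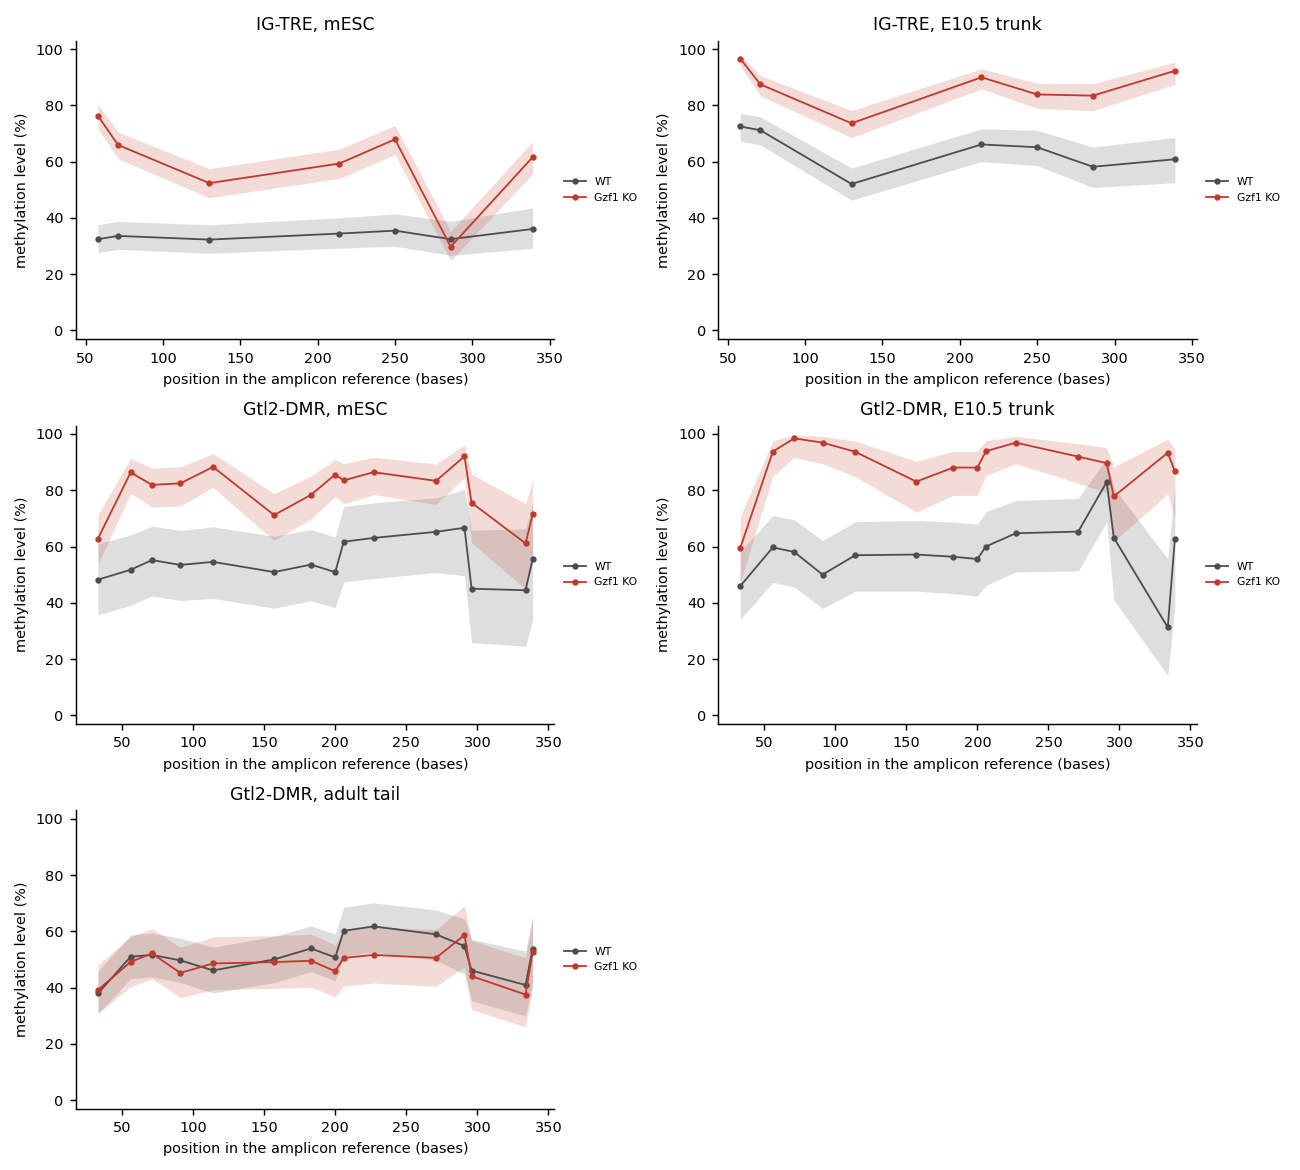
Methylation level (%, vertical axis) at each CpG by position in the amplicon reference (bases) for the IG-TRE and the Gtl2-DMR, wild type in grey and Gzf1 knockout in red, with Wilson intervals as bands. The knockout lies above wild type at all 15 Gtl2-DMR CpGs in mESC and trunk, and at 4 of 15 in adult tail.

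In MII oocytes, which hold only maternal copies, the IG-CGI was almost unmethylated in the wild-type library and largely methylated in both Gzf1 knockout libraries. The wild-type library had a mean of 0.301%, and all of its 1178 reads were mostly unmethylated. The Gzf1 knockout mean was 90.2% ± 8.59 (SD, n = 2), with 96.3% in library 1 and 84.1% in library 2. Against wild type, 28 of 29 CpGs were higher in library 1 and 29 of 29 in library 2, and CpG 251 had the largest rise, from 0 to 99.8%. Mostly methylated reads made up all 1472 reads of library 1 and 550 of 786 reads of library 2 (Wilson interval 66.7% to 73.1%), and neither had a mostly unmethylated read (0 of 1472 and 0 of 786, which allows up to 0.204% and 0.382%).

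The knockout oocyte libraries differed in detail. CpG 231, chosen after its values were seen, was methylated in 1 of 1412 calls in library 1 and in 82.8% of calls in library 2, and the other 28 CpGs of library 1 were at 99.1% to 100%. In library 1, 1005 of 1068 reads called at every CpG shared the pattern with CpG 231 alone unmethylated, and 68 of 541 such reads of library 2 had it too. The rise was far larger than the SD between the knockout libraries, but an exact permutation test of 2 against 1 libraries gave a two-sided p of 0.333, the smallest this design allows. The labels do not say whether the replicates came from separate females, so their spread may be technical.

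In adult tail the IG-CGI was more methylated in the Gzf1 knockout mouse. The mean was 51.9% in the wild-type and 80.6% in the knockout library, a difference of 28.7 points (95% interval 26.3 to 31.1), and all 29 CpGs were higher. CpG 147 had the largest rise, from 43.9% to 79.3%. Mostly methylated reads went from 45.2% (Wilson interval 42.8 to 47.5) to 79.3% (77.2 to 81.3), and mostly unmethylated reads from 44.0% to 9.48%. With a minimum of 30 points, 11 CpGs were called.

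The Gzf1 knockout pup found dead at birth also had a more methylated IG-CGI than the adult wild-type tail. Its mean was 75.8%, which was 24.0 points higher (95% interval 21.5 to 26.4), with 21 of 29 CpGs higher and the largest rise at CpG 101, from 50.3% to 89.2%. Reads with between 30% and 70% of calls methylated made up 25.7% of its reads (Wilson interval 23.2 to 28.3), against 10.8% in the adult wild-type tail. Age and genotype were compared together here, and 6 CpGs were called with a minimum of 30 points.

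Heterozygous mice born to Gzf1 knockout mothers and wild-type fathers had tail methylation slightly below that of the wild-type mouse and far below that of the knockout mouse. They were grouped as adult tail, but the submitters' names call them pups, so age may differ from the adult wild-type tail. Their libraries were also in other sequencing orders than the wild-type tail, so order and genotype were not separated. The mean over the animals was 48.6% ± 2.78 (SD, n = 5), with a range of 46.9% to 53.4%, against 51.9% in the wild-type tail and 80.6% in the knockout tail. The difference from wild type was -3.32 points (95% interval over reads -4.60 to -1.94), and averaged over the animals all 29 CpGs lay below wild type by value. This interval is too narrow, because the single wild-type library was resampled separately for each animal. The wild-type mean alone had an interval of 49.9% to 53.8%. Of the 5 animals, number 2 in running order lay above wild type, by 1.51 points, and the other 4 below. The difference exceeded the SD between animals slightly, and an exact two-sided permutation test gave p = 0.333, where the smallest p possible is 0.167. No CpG was called in all 5 animals by Fisher's exact test, and none had an unadjusted p under 0.05 in all 5, although 2 to 25 of the 29 CpGs did in single animals. The largest difference was at CpG 216, with 48.3% against 54.1%. Mostly methylated reads made up 40.9% ± 3.86 and mostly unmethylated reads 47.8% ± 3.40 (SD, n = 5), against 45.2% and 44.0% in wild type.

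At the Gtl2-DMR of adult tail the library labelled Gzf1 knockout was not more methylated than wild type. The mean was 51.2% in the wild-type and 48.3% in the knockout library, a difference of -2.87 points (95% interval -13.2 to 6.47). No CpG of 15 was called by Fisher's exact test, and none had an unadjusted p under 0.05. The largest difference was at CpG 227, with 51.6% in the knockout and 61.7% in wild type. Mostly methylated reads were 39.4% in wild type (Wilson interval 31.8 to 47.7) and 37.6% in the knockout (29.1 to 47.0). The upper bound of the difference, 6.47 points, lies below the lower bounds in mESC, 12.6, and in trunk, 19.9. The title of this library names wild type as well as Gzf1 knockout, and its group follows the genotype label and the library name.

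Over the 4 sources with a wild-type and a Gzf1 knockout library of the IG-CGI, the difference was positive in each. It ranged from 28.7 points in adult tail to 89.9 points in oocytes, with a mean of 48.3 ± 28.2 points (SD, n = 4). An exact two-sided sign-flip permutation test gave p = 0.125, the smallest that 4 differences allow. Without the oocytes the mean was 34.4 points.

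**Figure D3:**
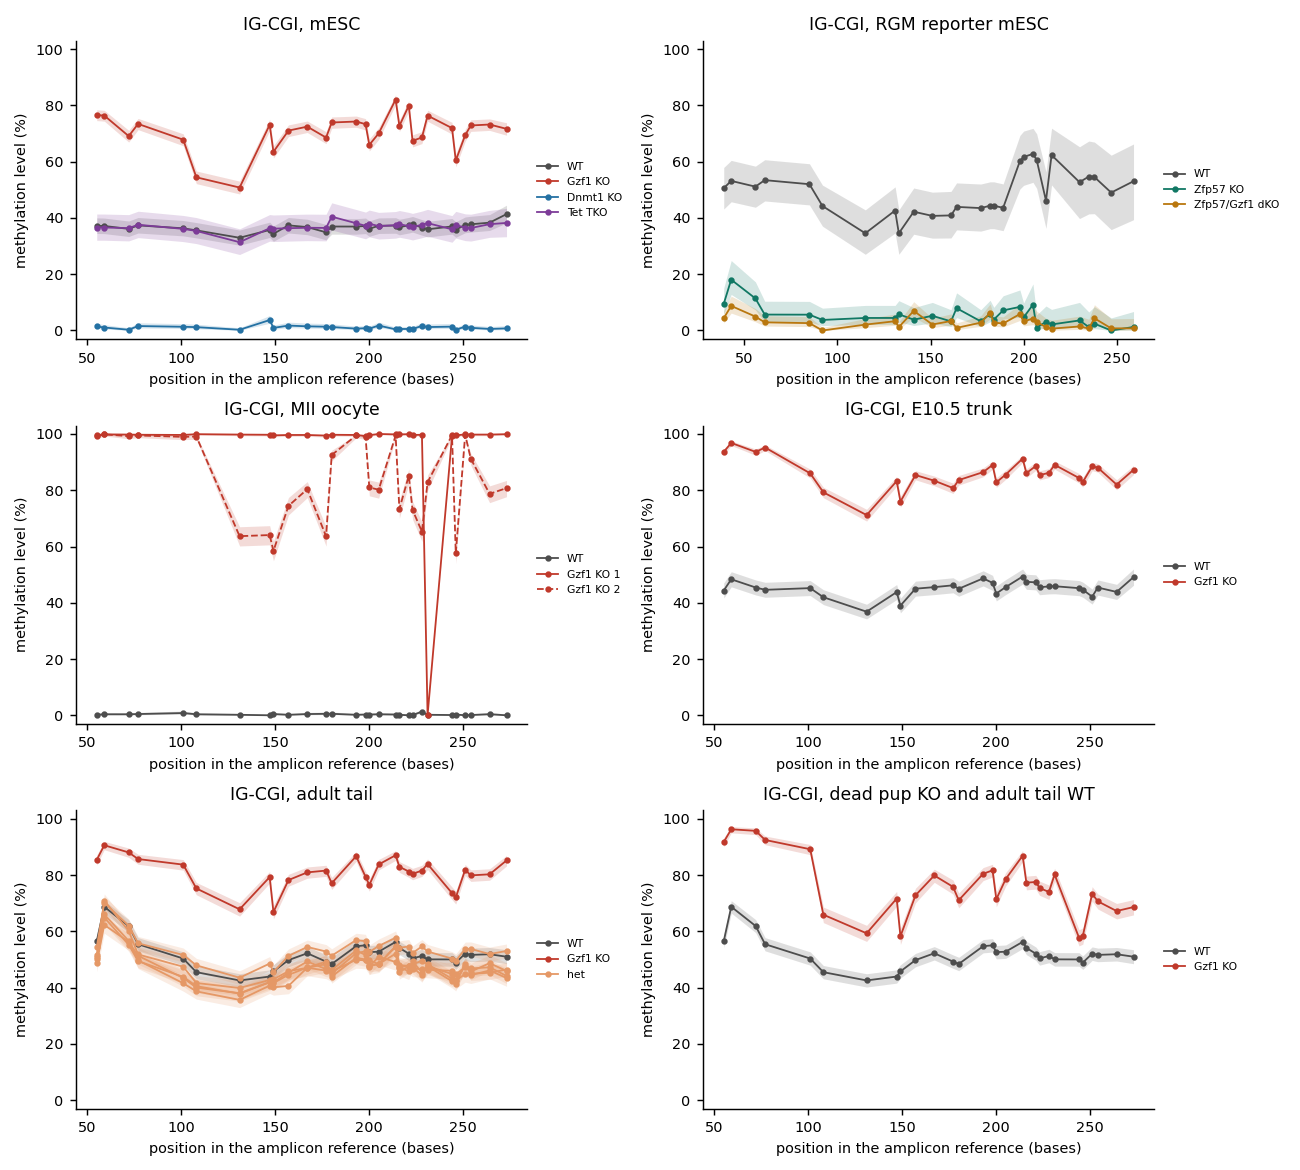
Methylation level (%, vertical axis) at each CpG of the IG-CGI by position in the amplicon reference (bases), with Wilson intervals as bands, in mESC, reporter mESC, MII oocytes, trunk, adult tail and dead pup. The Gzf1 knockout lies above wild type at all 29 CpGs in mESC, trunk and tail, and CpG 231 of oocyte knockout library 1 stands at 0.0708%.

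The size of the gain at the IG-CGI varied from CpG to CpG. The difference per CpG ran from 17.9 to 44.8 points in mESC, from 34.3 to 50.6 in trunk, from 78.2 to 99.8 over the 28 called CpGs in oocytes, from 21.1 to 35.4 in adult tail and from 7.73 to 38.9 in the dead pup. In oocytes CpG 231 had a mean difference of 41.3 points, which came from library 2 alone. Between the lower and the higher positions of the amplicon, the mean difference was 31.6 and 34.7 points in mESC, 42.6 and 39.9 in trunk, 92.4 and 88.6 in oocytes, 28.1 and 29.0 in adult tail, and 27.3 and 22.2 in the dead pup. At the IG-TRE in mESC, 3 of the lower 3 CpGs and 3 of the higher 4 were called higher, the exception being CpG 286. These splits by position were not tested.

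**Figure D4:**
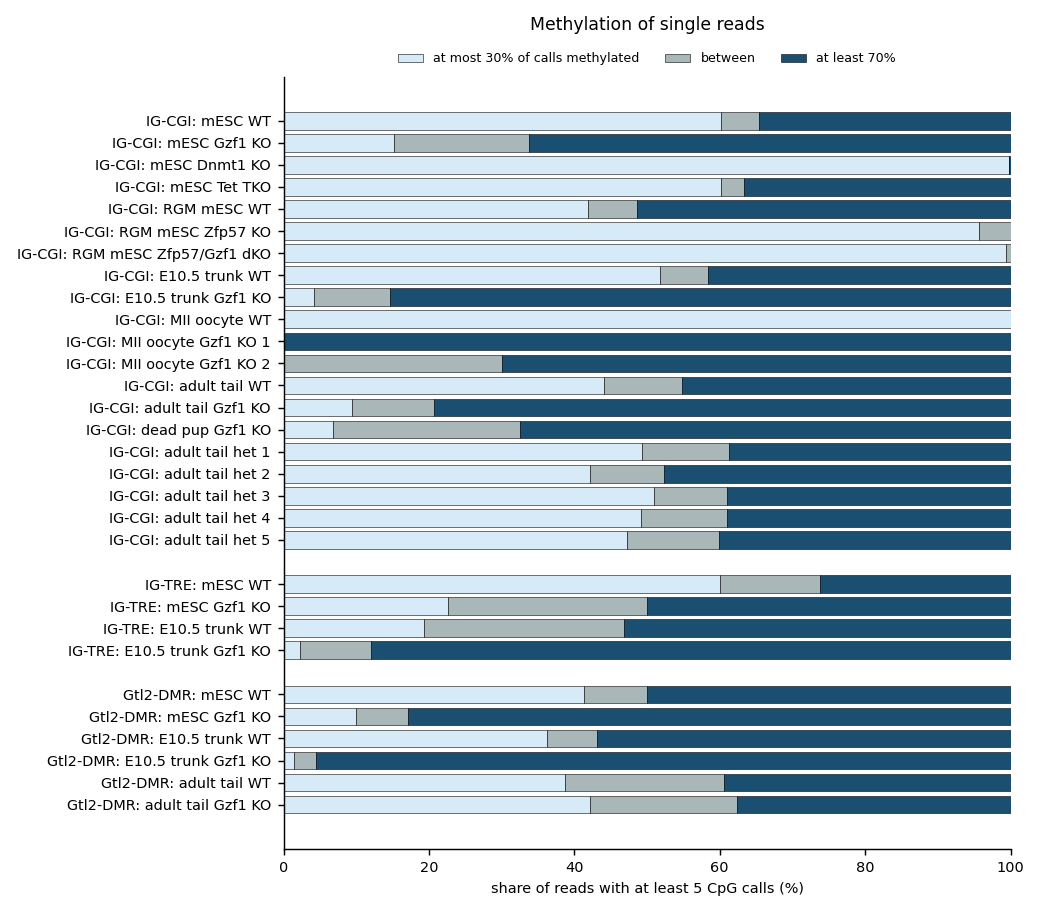
Share of reads (%, horizontal axis) with at least 5 CpG calls in each library that were mostly unmethylated (at most 30% of calls methylated), between, or mostly methylated (at least 70%). Mostly unmethylated reads at the IG-CGI are 60.2% in wild-type and 15.2% in Gzf1 knockout mESC, and 51.7% and 4.20% in trunk.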

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

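The test of a wrong label below was chosen after the result was seen. The change at the Gtl2-DMR with loss of Gzf1 differed between sources. The Gzf1 knockout minus wild-type difference in mESC exceeded that in adult tail by 27.6 points (95% interval over reads 11.4 to 44.1), and that in trunk exceeded it by 33.7 points (20.1 to 48.4). These intervals compare single libraries, and source, animal and sequencing order change together.

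Of the explanations for the absent rise in the adult tail, too few reads was judged by the lower bound of the trunk minus adult difference, 20.1 points. This is the interval given above, so it adds no separate evidence. It speaks against counting error of reads alone. PCR reads are not independent molecules, so too few starting molecules stays open. Reads that stop early are opposed by the adult difference among reads called at 50% or more of the CpGs, -3.44 points, whose upper bound of 6.74 lies below the trunk lower bound of 19.9. A wild-type tail under the knockout label could give the adult difference of -2.87 points, and this cannot be told apart from a tail that lacks Gzf1 and kept its Gtl2-DMR level, since the title of the library names both genotypes. Against it, the submitters' naming gives this library the same code as the IG-CGI library labelled knockout, which stood at 80.6% against 51.9% in wild type, but no label says that the codes mark animals, so a wrong label stays open. A loss of the gain with age or in tail tissue stays open and untested.

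Heterozygous animal 2 stood apart from the other 4 in mean IG-CGI level, at 53.4%, and in the share of mostly methylated reads, at 47.7%. Its gap to the nearest animal exceeded the critical value of Dixon's test in 2 of the 4 measures examined. Chance alone does this in about 1 of 20 groups for a single test, and more often when 4 overlapping measures are searched on their high and low sides, as here. Its values lie near those of the wild-type tail, 51.9% and 45.2%.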

How the results depend on the processing

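No mean difference with an interval that left out 0 changed sign under any alternative, and coverage minimums, pooling of calls, reads with at least 5 calls, reads called at 50% or more of the CpGs (chosen after seeing the data) and calls at every position left each mean difference within its interval or SD. Counting identical read patterns once moved 8 of the 16 mean differences: to 16.0 points in mESC IG-CGI, 11.5 in mESC IG-TRE, 25.7 in trunk IG-CGI and 15.6 in trunk IG-TRE for the Gzf1 knockout, to -51.4 for Dnmt1, and in reporter cells to -52.8 for Zfp57, -57.2 for the double knockout and -4.46 for the double against the Zfp57 knockout. It also moved the called CpGs to 7 in mESC IG-CGI, 2 in mESC IG-TRE, 0 in mESC Gtl2-DMR and 1 in trunk IG-TRE. By construction this setting removes repeats of fully methylated and fully unmethylated reads and weights reads with scattered calls. A minimum difference of 30 points left 3 calls in mESC IG-TRE, 4 in mESC Gtl2-DMR, 1 in trunk IG-TRE, 11 in adult tail IG-CGI and 6 in the dead pup, since fewer CpGs reach it. All other values, 110 of 119 counts of calls and 111 of 119 mean differences, stayed within 1.5 times or within their error. Leaving out a replicate gave 83.8 to 96.0 points and 28 to 29 calls in oocytes, and -4.53 to -2.90 points and 0 calls in heterozygous tails. Leaving out a source gave 34.4 to 54.8 points across sources. Of the read shares, 51 of 120 moved beyond their Wilson interval, mostly with a single bound of 50% (20) or identical patterns counted once (18). No paired analysis was possible because 14 of the 16 comparisons had 1 library per group and the others had 1 wild-type library. Depth limits the Gtl2-DMR most, with 60 to 160 reads.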

Other observations

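All tests in this part were chosen after the result was seen, except that of few starting molecules. CpG 131 of the IG-CGI was the least methylated CpG in all 3 wild-type libraries of mESC, trunk and tail, and in 2 of the 4 Gzf1 knockout libraries of mESC, trunk, tail and pup. Within mostly methylated reads it stood at 80.7% to 89.4% in wild type, where the median of the other CpGs was 96.1% to 96.5%, and at 70.7% to 82.1% in the knockouts, where that median was 90.5% to 94.6%. The difference between the genotypes within mostly methylated reads was not tested.

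The Gzf1 knockout oocyte libraries held few read patterns. At 304 reads per library, the 5 largest families of patterns (reads within 2 CpGs of a more common pattern) held all reads of library 1 and 94.0% of library 2, against 67.3% in the trunk knockout, which has a like mean level (85.9% against 84.1% in library 2) and the highest share among the other Gzf1 knockouts. A sequence variant at CpG 231 fixed in the knockout line is opposed by its level elsewhere, at least 80.2% in library 2 and the knockout trunk, tail and pup. Those levels do not bear on a sequence change limited to the source of library 1, which stays open. Few starting molecules may account for the pattern, and so may molecules shared between the libraries, which were in 1 sequencing order, since the main pattern of library 1 holds 12.6% of the reads of library 2 and at most 0.577% in the other Gzf1 knockouts. Without reads close to that pattern library 2 has a mean of 82.6%, and a pattern that is real in both pools stays open, as few families also occur in libraries from cells (96.1% of reads in the 5 largest for Tet triple knockout mESC at a mean level of 36.9%, 100% for Dnmt1 knockout mESC) and in wild-type oocytes (100%).

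Heterozygous tails lay near the wild-type level although the oocytes of Gzf1 knockout females were methylated. The 5 means ran from 46.9% to 53.4%, and the lower bound of the dead pup was 74.3%. Whether an oocyte level that rests on few molecules contributes cannot be decided here. The 5 largest families held at most 67.7% of reads in any heterozygous tail, a lower share than in both knockout oocyte libraries. That share also follows how uniform methylation is, with 100% in wild-type oocytes, so it does not measure the number of molecules. Neither knockout oocyte library held a mostly unmethylated read. The other candidate, that methylation of the maternal copy is lost after fertilisation where the paternal Gzf1 copy is intact, is a hypothesis without a test here, since no embryo from this cross was analysed here.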
